A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

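Poly(A) RNA of Saccharomyces cerevisiae strain BY4743, a diploid laboratory strain, was measured in 8 libraries. The labels give 2 states and 2 media with 2 replicates each. One state carries the natural [SMAUG+] prion, an inheritable form of Vts1, the yeast homologue of the RNA-binding protein Smaug; the other is its selectively cured counterpart. Per the labels, cells grew to saturation for 48 h in preSPO medium, 5 ml of a 10 ml culture was harvested, and the other 5 ml went into SPO medium for 14 h. A letter in the sample descriptions, A for replicate 1 and C for replicate 2, was read as the culture, so that preSPO and SPO libraries of one state and number come from one culture by the labels. MET17 goes against this reading for prion replicate 2, with 3867 counts in preSPO and 1 in SPO medium, and for cured replicate 1, with 0 and 447, so fits with the culture as a block rest on an open point. The independence of replicates rests on the labels alone. The design text of the series speaks of VTS1 overexpression and a VTS1 deletion, which the sample labels do not name. Groups follow the sample labels, and VTS1 was counted in all 8 libraries.

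Per the submitters' processing notes, the deposited tables were made with kallisto against build R64; the version and index are not given in the sources used here. Each of the 8 tables lists 6713 targets with a length, an effective length, an estimated count and a TPM value. The estimated counts, as deposited, are kallisto's expected counts and need not be whole; they were rounded to whole numbers before testing. The TPM values, as deposited, were made by the authors' kallisto run and sum to between 1000000 and 1000001 in each library. Because 6711 targets have a length divisible by 3, lengths are coding lengths, and reads in untranslated regions were not assigned unless they overlapped a coding sequence. Reads from near-identical copies are divided by kallisto's estimate, so values for Ty elements and for paralogous histone, ribosomal protein and PAU genes are uncertain. The strand setting is not given in the sources used here, so reads of overlapping or antisense genes are not told apart. Of the targets, 6026 (89.8%) matched a locus tag in the reference symbol table for the R64 assembly, whose coordinates are used.

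The sum of estimated counts ranged from 4650285 to 71684784 per library. For the fold limits of Ty reading frames and for plotting MET17, 0 counts were given a floor of 3 counts. This floor corresponds to 0.0551 to 0.680 CPM in single libraries on their effective library sizes. The tests and the MET17 rates used counts without a floor. Intervals and floors cover counting error only. In every library the largest target was TAR1, a reading frame in the ribosomal DNA, with 3.18% of counts (95% Wilson interval 3.17 to 3.19) in prion preSPO replicate 1 as the lowest share and 14.77% (14.76 to 14.77) in cured SPO replicate 2 as the highest. Libraries of a group were not duplicates of each other: the chi-square per degree of freedom of their counts ranged from 35.4 to 162.

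Tests used edgeR 4.0.16 quasi-likelihood F-tests (glmQLFit and glmQLFTest, robust=FALSE) in R 4.3.3 on a group-means model of all 8 libraries, with 4 residual degrees of freedom. TMM normalization and filterByExpr left 6346 genes, and two-sided p-values were adjusted by Benjamini-Hochberg over these genes, with calls at an adjusted p under 0.05. The contrasts were cured minus prion in each medium and over both media, SPO minus preSPO in each state, and the interaction. For 34 gene lists fixed before the data were examined, limma 3.58.1 camera was run with a preset correlation of 0.01 on log2 CPM (prior count 2), and Benjamini-Hochberg adjusted over the lists of a contrast; an estimated correlation and fry were run beside it. All calls by camera with the preset correlation were lost with the estimated correlation. Hairpins with a CNGG or CNGGN loop, the motif bound by the SAM domain of the Smaug family, were searched in coding sequences with a stem of 5 base pairs (Watson-Crick or G-U), and the median fold change of genes with a site was set against 10000 random lists matched on coding length and mean expression.

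Genes were named by a rule fixed before the data were examined. It takes VTS1 in every comparison; up to 10 genes with the largest and 10 with the smallest log2 fold change among calls with a standard symbol, a mean of at least 10 CPM on a side and no overlap of replicates (5 and 5 for the interaction); up to 4 members with the smallest p per list discussed; and markers of the strain and of haploid cells. Genes outside it are said to have been chosen after their values were seen. On data simulated from the real means and library sizes, the cured and prion comparison in preSPO medium recovered 60% of genes changed 2-fold and 100% of those changed 4-fold, with 6 calls among 6106 unchanged genes. The same test for SPO medium recovered 55% and 100%, with 3 such calls. Changes were seeded only in well-counted genes, and counts were drawn independently between genes, without libraries that stand apart. The rates may therefore not hold for the real libraries.

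Alternatives tried were other scalings (DESeq2-style size factors, upper quartile, library size), DESeq2 1.42.0, limma-trend on log2(TPM + 1), other filters, robust fitting, only the groups compared, other thresholds, leaving out each library, and fits with the replicate number or the culture as a block. Leaving out 2 pairs of libraries, leaving out TAR1 and YNL143C, and an additive model were chosen after seeing the data. Deviations of same-numbered libraries from their group means correlated across 5617 genes at 0.505 between the cured groups of both media and at 0.105 between the prion groups. Between states they correlated at 0.395 in SPO and at 0.213 in preSPO medium, so the replicate number also goes with values across states. With the replicate number as a block, cured against prion gave 142 calls in preSPO and 3 in SPO medium. The libraries were not paired unless the culture block is named. Other steps used Python 3.11.15 with scipy 1.17.1.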

Results

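The data set holds 8 poly(A) RNA libraries of the diploid yeast strain BY4743, 2 for each combination of state and medium. The state is either prion, the label for cells with the natural [SMAUG+] prion, or cured, the label for cells from which it was removed. The media are preSPO, a saturated culture after 48 h, and SPO, a sporulation medium in which cells were kept for 14 h. The estimated counts of replicates 1 and 2 summed to 6983349 and 9756821 in prion preSPO, 6246215 and 21796878 in cured preSPO, 9716969 and 15047701 in prion SPO, and 4650285 and 71684784 in cured SPO. The first principal component separated the media and held 87.1% of the variance over 5617 genes.

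VTS1, which encodes the protein of the prion (chromosome XV, 1011189 to 1012760, R64), was counted in every library. It stood at 45.2 ± 22.8 CPM (SD, n = 2) in prion preSPO and 56.7 ± 0.248 CPM in cured preSPO, and at 13.5 ± 0.382 CPM in prion SPO and 13.6 ± 3.27 CPM in cured SPO. By edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, the log2 difference of cured minus prion was 0.33 (SE 0.315, adjusted p = 0.594) in preSPO medium and -0.04 (SE 0.339, adjusted p = 1) in SPO medium. The preSPO difference was 0.96 without prion preSPO replicate 1 and -0.11 without prion preSPO replicate 2. From preSPO to SPO medium VTS1 fell by 1.74 on the log2 scale in prion libraries (SE 0.332, adjusted p = 0.00255; log2 -1.11 without prion preSPO replicate 1), and in cured libraries its edgeR log2 fold change was -2.11 (SE 0.338, adjusted p = 0.000959).

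MET17, a gene of sulfur assimilation for which BY4743 carries 1 deleted copy (chromosome XII, 732542 to 733876), did not follow the labels in SPO medium. In preSPO medium it had 3207 and 3867 counts in the libraries labelled prion and 0 and 1 in those labelled cured, so that the cured rate was 0.00835% of the prion rate (95% exact interval 0.000211 to 0.0465). In SPO medium, the library labelled prion replicate 1 had 1363 counts and the one labelled prion replicate 2 had 1, a rate of 0.0504% (95% exact interval 0.00128 to 0.281) of replicate 1. The library labelled cured SPO replicate 1 had 447 counts and the one labelled cured SPO replicate 2 had 13, or 0.236% (95% exact interval 0.124 to 0.407) of replicate 1 in rate. Comparisons of prion and cured follow the labels, and their directions rest on them. An exchange of prion SPO replicate 2 and cured SPO replicate 1, left open below, would mix the states within both labelled SPO groups. Few calls between states in SPO medium are then no sign that the states were alike. Among the other strain markers, LYS2 had a log2 difference of cured minus prion of -0.04 (SE 0.166) in preSPO and 0.16 (SE 0.171) in SPO medium, HIS3 had -0.15 (SE 0.257) and 0.02 (SE 0.261), and URA3 reached at most 1.07 CPM and LEU2 at most 0.213 CPM in any library.

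**Figure D1:**
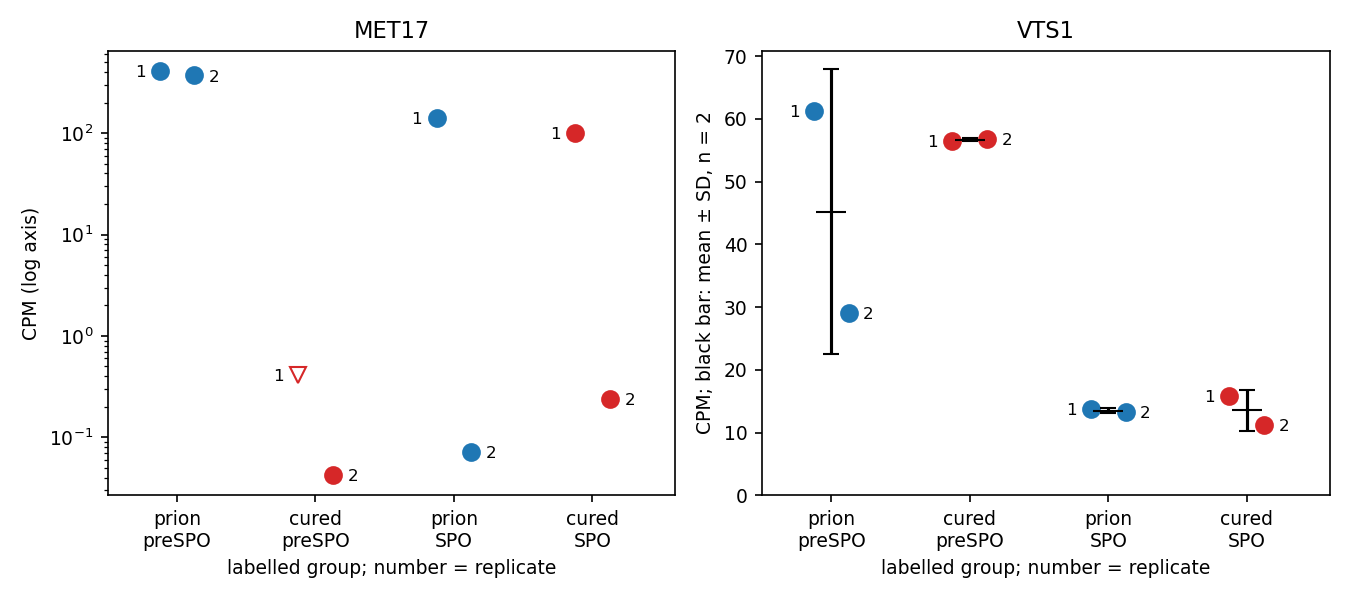
CPM of MET17 (left, log axis) and VTS1 (right, from 0) in the 8 libraries by labelled group, with the replicate number beside each point. The open triangle is cured preSPO replicate 1, which had 0 MET17 counts and is drawn at its floor of 3 counts, and the black bars on the right are means with SD (n = 2). MET17 had 1363 counts in the library labelled prion SPO replicate 1 and 1 in the one labelled prion SPO replicate 2.

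The first comparison asked how the cured state differed from the prion state in saturated preSPO culture. Of 26 sulfur assimilation genes 8 rose in the libraries labelled cured, with MET3, which encodes ATP sulfurylase, highest. The same libraries had 0 and 1 counts of MET17, so the cured state and the absence of MET17 could not be told apart. Of 31 cell wall genes 3 fell, and of 11 histone genes 2. In all, 59 of 6346 genes were called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 29 higher and 30 lower in cured.

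Of the 26 measured members of the sulfur list, 8 rose, 0 fell and 18 were not called, and 13 rose when adjusted over the list alone. MET3 had a log2 fold change of 2.39 (SE 0.353, adjusted p = 0.0297, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SUL2, a sulfate permease, rose by 1.91 (SE 0.222), MET32, a transcription factor of the pathway, by 1.72 (SE 0.177), MET1, of siroheme synthesis, by 1.62 and MET14, the adenylylsulfate kinase, by 1.44. Each was higher in both cured libraries than in either prion library, which the naming rule required of all but MET14. Of all 6346 genes, 46.9% had no overlap between the replicates of the states here. The list was called by limma camera (adjusted p = 3.09e-06, Benjamini-Hochberg; adjusted p = 0.595 with an estimated correlation). MET17, which is not a member of the list, was not called (adjusted p = 0.138 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, with 1.39e-08 to 0.545 over the alternatives). MET17 nonetheless had 0 and 1 counts in the cured and 3207 and 3867 in the prion preSPO libraries. Its absence coincided with the cured state, so the sulfur result cannot be tied to the state alone. Other genes that rose were PAU23, a seripauperin, by 2.19, RAD59, a recombination gene, by 2.17, FMO1, a flavin monooxygenase, by 1.74, HMX1, the heme oxygenase, by 1.67, GRX8, a glutaredoxin, by 1.65, and SER33, an enzyme of serine synthesis, by 1.56.

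**Figure D2:**
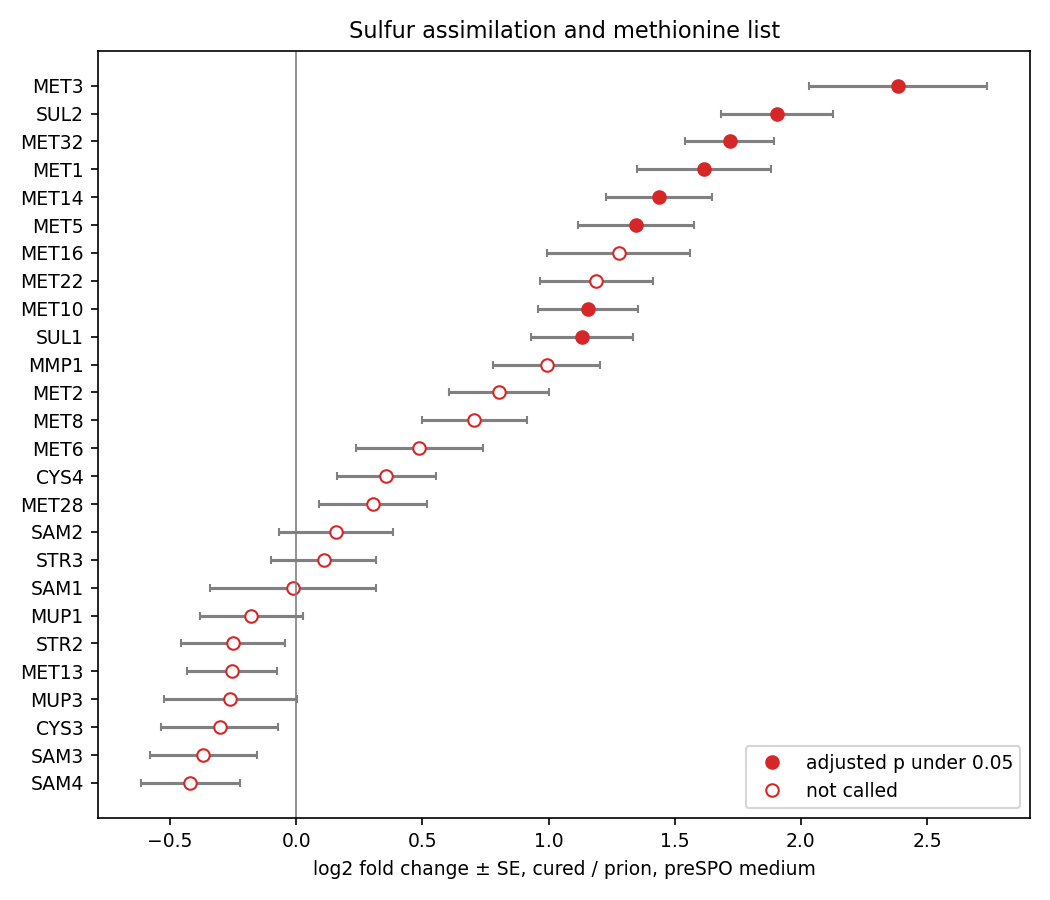
Log2 fold change (horizontal axis) of the 26 members of the sulfur list, cured over prion in preSPO medium, with standard errors as bars. Filled points mark the 8 members called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; MET3 lies highest at 2.39.

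Of 11 histone genes, 0 rose, 2 fell (HTA2 at -1.48 and HHT2 at -1.38 on the log2 scale) and 9 were not called, and 8 fell when adjusted over the list alone. The list was called by limma camera (adjusted p = 2.70e-06, Benjamini-Hochberg; adjusted p = 0.595 with an estimated correlation). Of 31 cell wall genes, 0 rose, 3 fell and 28 were not called, those that fell being TIP1 (-1.51), CIS3 (-1.28) and GAS1 (-1.24). Adjusted over the list alone, 10 cell wall genes fell and 2 rose (limma camera adjusted p = 2.70e-06, Benjamini-Hochberg; adjusted p = 0.595 with an estimated correlation). SCW4, a cell wall glucanase, had a log2 fold change of -1.75 (SE 0.189), ECM33, a cell wall protein, of -1.75, TUB2, the beta-tubulin, of -1.59, TOS6 of -2.12, SFG1, a regulator of growth form, of -1.54, SIM1 of -1.45 and CIP1, a cyclin-dependent kinase inhibitor, of -1.38. RNR1, the ribonucleotide reductase large subunit, had -2.04 and was the 1 gene called among 32 of the G1/S list, of which 4 fell when adjusted over the list alone (limma camera adjusted p = 0.000468, Benjamini-Hochberg; adjusted p = 0.595 with an estimated correlation).

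Of 34 oxidative phosphorylation genes 0 rose and 0 fell, with 9 lower when adjusted over the list alone (median -0.54, limma camera adjusted p = 9.24e-07, Benjamini-Hochberg; adjusted p = 0.610 with an estimated correlation). ACO1, the aconitase, had -1.23 on the log2 scale and was the 1 gene called among 16 of the tricarboxylic acid cycle (camera adjusted p = 0.00152, Benjamini-Hochberg; adjusted p = 0.595 with an estimated correlation). Of 10 haploid-specific genes, which mark haploid cells, 0 rose and 0 fell, and 3 fell when adjusted over the list alone (limma camera adjusted p = 0.000529, Benjamini-Hochberg; adjusted p = 0.595 with an estimated correlation). In total camera called 12 of 34 lists, while 0 were called with an estimated correlation and 0 by fry; the lists named here kept their camera call without any single library.

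Genes named for the largest changes in preSPO medium kept their call without cured SPO replicate 1 or cured SPO replicate 2. SPO libraries are not compared here and enter through steps shared by all libraries, such as the estimate of spread. The calls of this comparison depended on other single libraries. The count was 1 without cured preSPO replicate 1, 1 without cured preSPO replicate 2, 2 without prion preSPO replicate 2, and 0 without prion SPO replicate 1 and 0 without prion SPO replicate 2 (with 955 and 949 genes at an unadjusted p under 0.05 by edgeR), but 468 without prion preSPO replicate 1. DESeq2 gave 432 calls, a fit with the replicate number as a block 142, and limma-trend on log2 TPM 94, 67 of them higher, with the median over all genes at 0.10. Prion preSPO replicate 2 stood apart from the other preSPO libraries, at -38.4 on the first principal component against -57.6 to -47.8. Across genes, its Spearman correlations with the SPO libraries were 0.710 to 0.733, against 0.608 to 0.668 for the other preSPO libraries. Prion preSPO replicate 1 correlated at 0.972 with cured preSPO replicate 1 and at 0.955 with prion preSPO replicate 2. Without prion preSPO replicate 2 the list median moved from -1.01 to -0.57 for histones, -0.63 to -0.29 for the cell wall, -0.54 to -0.35 for oxidative phosphorylation, -0.39 to -0.20 for the tricarboxylic acid cycle and -0.60 to -0.26 for haploid-specific genes. Without prion preSPO replicate 1 that of G1/S genes moved from -0.22 to -0.34. On log2 TPM the medians were -0.41 for the cell wall, -0.26 for the tricarboxylic acid cycle, -0.30 for haploid-specific and -0.09 for G1/S genes.

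The same comparison, whose labelled groups would mix the states if libraries were exchanged, gave few calls in SPO medium, after 14 h. There 2 of 6346 genes were lower in cured, and both are reading frames of Ty elements, the retrotransposons of yeast. They were called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.000280 for each), and 154 genes had an unadjusted p under 0.05. The frames are YDR316W-A (chromosome IV, 1096064 to 1097386) and YGR161C-C (chromosome VII, 821693 to 823015), named here after their values were seen. Each had 657 and 849 counts in the libraries labelled prion and 0 in both labelled cured. Against a floor of 3 counts over the group this was at least 1250-fold lower in cured, a limit that covers counting error only. With the shallower cured SPO replicate 1 alone this limit was 93.4-fold, and with cured SPO replicate 2 alone 1150-fold. In preSPO medium each had 0 counts in both prion libraries and 1 and 2 in cured. Both frames have equal counts in every library, as when reads of near-identical copies are divided, so the source among the Ty copies is not resolved. The fold limits therefore do not cover reads assigned to another copy, and the 2 frames are not separate results.

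Camera called 8 of 34 lists in SPO medium, with 0 called with an estimated correlation and 0 by fry, and no member of them passed over all genes. Glycolysis and fermentation genes had a median of 0.30 (limma camera adjusted p = 0.000113, Benjamini-Hochberg; adjusted p = 0.948 with an estimated correlation). It was 0.13 with library size scaling and 0.04 on log2 TPM. Without cured SPO replicate 1 the median was 0.03 (adjusted p = 0.239). Early meiotic genes had a median of -0.24 (camera adjusted p = 0.000958, Benjamini-Hochberg; adjusted p = 0.763 with an estimated correlation), of -0.42 with library size scaling, of -0.38 on log2 TPM and of -0.14 without cured SPO replicate 1. The sulfur list had a median of 0.19, which turned to -0.02 with library size scaling and -0.09 on log2 TPM (limma camera adjusted p = 0.0358, Benjamini-Hochberg; adjusted p = 0.948 with an estimated correlation). Without cured SPO replicate 2 the sulfur median was 0.06. Under these 2 scalings the median over all genes lay at -0.17 and -0.23. Leaving out cured SPO replicate 1 ended 6 of the 8 list calls, cured SPO replicate 2 ended 4, prion SPO replicate 1 ended 2 and prion SPO replicate 2 ended 3. Without cured SPO replicate 1 the count of genes was 11, and DESeq2 called 15 and limma-trend on log2 TPM 10.

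The effects of state in the 2 media were then set side by side, over libraries that the media do not share. Across 6346 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.033 and a Spearman correlation of -0.06. Of the 59 preSPO calls 26 (44.1%) had the same sign in SPO medium. Mixed states in the SPO groups, which the MET17 counts leave open, would hide a shared effect here and in the mean over both media. The mean over both media gave 0 calls with edgeR (661 genes at an unadjusted p under 0.05, 68 calls by DESeq2 and 18 by limma-trend on log2 TPM), with 6 without prion preSPO replicate 1, 1 without cured preSPO replicate 1, 1 without cured preSPO replicate 2 and 7 without cured SPO replicate 1. For this mean limma camera called 11 of 34 lists, 0 of them with an estimated correlation.

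The interaction asked which genes answered SPO medium differently in the 2 states. It was called for 1 gene, AI2, a reading frame in a mitochondrial intron (chromosome MT, 13818 to 18830), with a log2 value of 2.52 (SE 0.258, adjusted p = 0.0341, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). AI2 stood at 168 ± 16.8 CPM (SD, n = 2) in prion preSPO, 68.4 ± 4.18 CPM in cured preSPO, 266 ± 24.0 CPM in prion SPO and 621 ± 46.6 CPM in cured SPO. How much RNA without poly(A) tails each library held was not measured, which limits the reading of AI2 as a mitochondrial target. It was lower in cured in preSPO medium (log2 -1.30, adjusted p = 0.0297) and higher in SPO medium without passing the threshold there (log2 1.23, adjusted p = 0.101, both by edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The call was lost without cured preSPO replicate 1, cured preSPO replicate 2, prion preSPO replicate 2, prion SPO replicate 1, prion SPO replicate 2 or cured SPO replicate 2, and with the culture as a block. The count was 44 without prion preSPO replicate 1 and 4 without cured SPO replicate 1, and DESeq2 gave 131.

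The comparison of the media asked how cells of each state answered 14 h in sporulation medium. In SPO medium 1660 genes rose and 1720 fell in prion-labelled libraries, and 1816 rose and 1817 fell in cured-labelled ones, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of 17 genes of the glyoxylate cycle and gluconeogenesis, the list with the highest median, 16 rose and 1 fell in prion libraries (limma camera adjusted p = 0.181 with an estimated correlation). Of 68 ribosome biogenesis genes 58 fell and 1 rose in prion libraries (limma camera adjusted p = 0.350 with an estimated correlation). Of 56 mitochondrial ribosomal protein genes 20 rose and 4 fell in prion libraries, and 15 rose and 13 fell in cured ones, with medians of 0.33 and 0.07 that turned to -0.28 and -0.89 on log2 TPM and, in cured libraries, to -0.32 with library size. The median over all genes was negative too under both scalings, so a change of sign alone does not place a list below other genes.

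FBP1, fructose-1,6-bisphosphatase, had a log2 fold change of 7.96 (SE 0.292) in prion and 7.92 (SE 0.290) in cured libraries. ADY2, an acetate transporter, rose by 9.96 and 9.30, ADH2, the alcohol dehydrogenase used in ethanol oxidation, by 8.70 and 8.24, and PHO89, a phosphate transporter, by 9.77 and 8.51. SIP18 rose by 11.27 and 9.86, RGI2 by 10.36 and 9.05, GRE1 by 9.70 and 8.71, SPG1 by 8.27 and 9.28 and SPS100, a spore wall gene, by 7.89 and 8.04, in prion and cured libraries respectively. YAT1, a carnitine acetyltransferase, rose by 8.53 in cured libraries and SPG4 by 7.77 in prion libraries. Both also stood higher in SPO medium in the other state. Mean YAT1 went from 5.09 to 846 CPM in prion libraries, and mean SPG4 from 39.8 to 3758 CPM in cured ones.

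Of 17 glyoxylate and gluconeogenesis genes, 16 rose and 1 fell in each state, and the list was called by limma camera in prion (adjusted p = 1.35e-11, Benjamini-Hochberg) and cured libraries (adjusted p = 9.34e-11; adjusted p = 0.181 and 0.203 with an estimated correlation). Of 16 tricarboxylic acid cycle genes 16 rose in prion libraries and 15 in cured ones, where 1 was not called. Of 34 oxidative phosphorylation genes 30 rose, 2 fell and 2 were not called in prion libraries, against 31, 1 and 2 in cured ones, with COX4 at 1.89 and 2.58. Transcripts of the 28 mitochondrial targets took between 0.161% and 0.289% of the counts in the preSPO libraries and between 1.58% and 2.85% in the SPO libraries. TAR1 also took a larger share in SPO libraries, 10.64% to 14.77% against 3.18% to 8.22%. How much RNA without poly(A) tails each library held was not measured, so the mitochondrial shares do not show higher expression by themselves. Of 37 beta-oxidation and peroxisome genes 23 rose and 3 fell in prion libraries, and 22 rose and 5 fell in cured ones, where the list median turned from 0.73 to -0.23 on log2 TPM. POX1, the acyl-CoA oxidase, rose by 5.56 and 5.37. In the quiescence list of 20 genes 16 rose in each state, and 1 fell in prion libraries. Limma camera called the tricarboxylic acid cycle, oxidative phosphorylation, beta-oxidation and quiescence lists in both states. With an estimated correlation their adjusted p = 0.203, 0.350, 0.252 and 0.350 in prion and 0.245, 0.451, 0.394 and 0.451 in cured libraries (limma camera, Benjamini-Hochberg).

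Meiotic genes rose in part. Of 13 meiotic regulators 11 rose in prion libraries and 9 in cured libraries, with 0 fallen, and in cured libraries the list median turned from 0.82 to -0.15 on log2 TPM. The median over all genes also turned negative on log2 TPM in both states, which bears on each such turn given here. IME1, the inducer of meiosis, rose by 3.17 and 2.84 and RIM4 by 2.72 and 3.27. The list of regulators was not sorted by whether a member promotes or represses meiosis, so its counts do not measure entry into meiosis. RME1, which it shares with the haploid-specific list, had means of 28.2 CPM in prion preSPO and 50.4 CPM in prion SPO. In cured libraries they were 14.5 CPM in preSPO and 46.5 CPM in SPO medium. Of 30 early recombination and synapsis genes 17 rose and 3 fell in prion libraries, and 16 rose and 4 fell in cured ones, where the list median turned from 0.69 to -0.28 on log2 TPM. DMC1 stood at 3.45 and 3.35 and REC8 at 3.61 and 3.38. Of 33 middle sporulation genes 13 rose and 4 fell in each state, with medians of 0.26 and 0.51 that turned to -0.26 and -0.41 on log2 TPM. The middle genes had a limma camera adjusted p = 0.0463 in prion and 0.0644 in cured libraries (Benjamini-Hochberg; adjusted p = 0.350 and 0.451 with an estimated correlation), and the prion call was lost without prion preSPO replicate 2 (median 0.45), prion SPO replicate 2, cured SPO replicate 1 or cured SPO replicate 2. Spore wall genes rose in 9 of 19 cases in prion and in 10 in cured libraries, where 1 fell and the median turned from 0.89 to -0.05 on log2 TPM. Limma camera called the regulators, the early genes and the spore wall genes in both states, and with an estimated correlation their adjusted p = 0.203, 0.203 and 0.203 in prion and 0.245, 0.343 and 0.326 in cured libraries. Of 10 haploid-specific genes 5 rose and 1 fell in prion libraries, and 6 rose and 1 fell in cured ones (limma camera adjusted p = 0.218 and 0.0110, Benjamini-Hochberg; adjusted p = 0.684 and 0.451 with an estimated correlation), and adjusted over the list alone 5 and 8 rose. Of 5 a-specific genes 1 rose in prion and 2 in cured libraries, as did 1 and 2 of 5 alpha-specific genes, and neither list was called by limma camera (adjusted p = 0.399 and 0.0912 for a-specific and 0.238 and 0.208 for alpha-specific genes, in prion and cured libraries). On log2 TPM the medians turned negative for the haploid-specific list in prion libraries and for the a-specific and alpha-specific lists in both states. Among their members, FUS3 rose by 3.00 in prion and 3.59 in cured libraries, AGA2, a gene of a-type cells, by 3.13 and 3.84, and STE3, a gene of alpha cells, by 1.70 and 1.26.

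Of 68 ribosome biogenesis genes 58 fell and 1 rose in prion libraries, and 59 fell and 1 rose in cured ones, with NOP1 at -2.11 and -1.94 and IMP3 at -3.96 and -3.50. Of 136 cytosolic ribosomal protein genes 100 fell and 3 rose in prion libraries and 85 fell and 6 rose in cured ones. Genes under nitrogen catabolite repression fell in 20 of 27 cases in prion and 21 in cured libraries, with DAL5, the allantoate permease, at -5.16 and -5.08, while 2 rose in each state, among them PUT4, the proline permease, at 3.13 and 3.25. Of 54 amino acid biosynthesis genes 37 fell in prion and 35 in cured libraries, and of 26 sulfur genes 18 and 22 fell, with SAM2 at -3.33 and -3.26. MET3 had -4.17 on the log2 scale in cured libraries. Limma camera called these lists in both states. With an estimated correlation their adjusted p, in this order, was 0.350, 0.427, 0.338, 0.350 and 0.257 in prion and 0.451, 0.492, 0.451, 0.451 and 0.245 in cured libraries (limma camera, Benjamini-Hochberg). Other genes that fell were DDR48 (-4.47), UGA4 (-4.28), DUR3 (-4.08), CHA1 (-4.04) and HXT2 (-3.99) in prion libraries, and HXT2 (-4.60), RCK1 (-4.28), DAL7 (-3.80) and SUT1 (-3.76) in cured ones. Genes were named by rank in each state, so a gene given for 1 state may have fallen in both, as RCK1 did (-3.905 in prion libraries). UGA4 stood at 871 CPM in prion preSPO replicate 1 and 205 CPM in prion preSPO replicate 2.

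**Figure D3:**
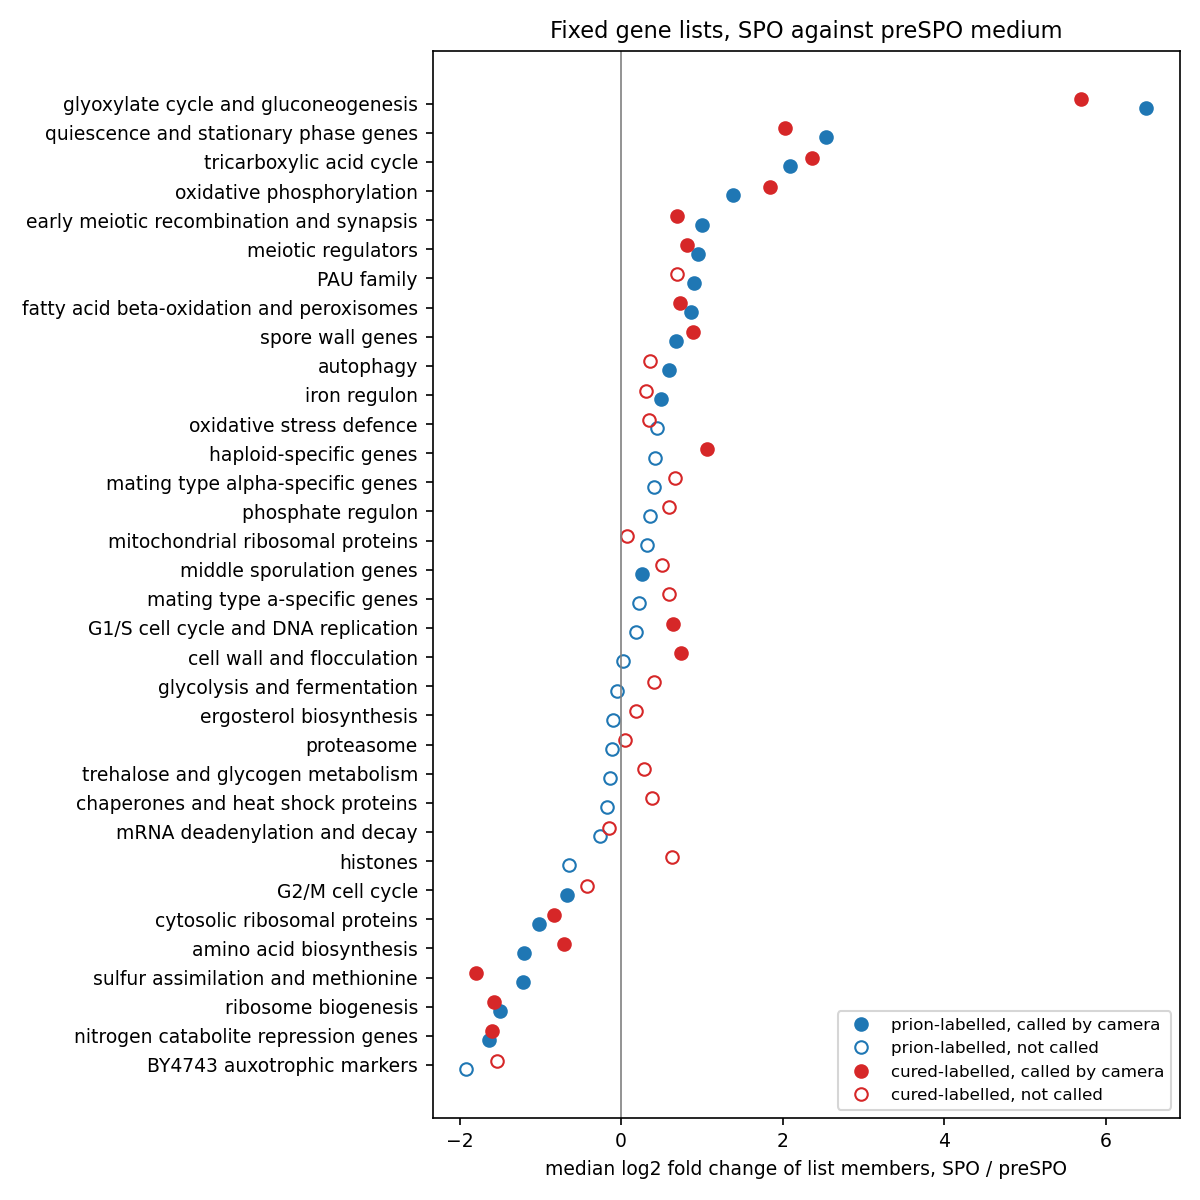
Median log2 fold change, SPO over preSPO medium, of the members of each of the 34 fixed lists (vertical axis) in prion-labelled (blue) and cured-labelled (red) libraries; filled points are lists called by limma camera with a preset correlation, none of which was called with an estimated correlation. Glyoxylate cycle and gluconeogenesis genes lie highest, at 6.50 and 5.69, and ribosome biogenesis genes at -1.50 and -1.58, with the same signs under every scaling tried, while many medians nearer 0 turned negative on log2 TPM, among them those of meiotic regulators, early meiotic, spore wall and beta-oxidation genes in cured libraries. The median over all genes also turned negative on log2 TPM in both states.

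The direction of change was shared by most genes called in prion libraries: of 3380 calls 3279 (97.0%) had the same sign in cured libraries, and the log2 fold changes had a Pearson correlation of 0.829 and a Spearman correlation of 0.873 across 6346 genes, which are not independent replicates. Both states called 1335 genes higher (475 for independent calls) and 1398 lower (492 for independent calls), and 12 genes in opposite directions.

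The balance of genes that rose and fell depended on the scaling. The median over all genes lay at 0.13 in prion and 0.15 in cured libraries with upper quartile scaling, at -0.17 and -0.37 with library size, and at -0.56 and -0.89 on log2 TPM, where 688 genes rose and 2496 fell in prion and 549 rose and 3464 fell in cured libraries. Without prion SPO replicate 2 the prion calls were 2192, and with the culture as a block, a reading of the labels that MET17 counts go against for prion replicate 2 and cured replicate 1, they were 3734 in prion and 3951 in cured libraries.

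Vts1 binds RNA hairpins with a CNGG loop, so genes with a stem of 5 base pairs, Watson-Crick or G-U, that closes a CNGG or CNGGN loop in their coding sequence were compared with others; untranslated regions were not searched. In preSPO medium the 1099 of 5827 genes with a hairpin had a median log2 fold change, cured over prion, of -0.06, below all 10000 random lists matched on coding length and expression. Limma camera on the same genes did not call them (unadjusted p = 0.332; unadjusted p = 0.513 with an estimated correlation). The 677 genes with a CNGG loop alone lay at percentile 0.9, the 506 with a stem of 6 base pairs at percentile 0.5 and the 199 with Watson-Crick pairs alone at percentile 5.7. A control loop, CNCC or CNCCN, gave a median of -0.03 at percentile 0.7 of its own random lists, so a low rank was not specific to the loop that Vts1 binds. In SPO medium the CNGG genes had a median of 0.03 at percentile 89.4 and the CNCC genes lay at percentile 97.8. Over both media the percentiles were 8.4 and 2.1. By limma camera the unadjusted p was 0.334 in SPO medium and 0.710 over both media.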

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

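No test in this part was chosen after its result was seen. The interaction of state and medium is given here wherever its own test passed, that is, where the response to SPO medium differed between the states. Such a difference can be the state difference of preSPO medium with its sign turned, and is then no separate result. AI2 had an interaction log2 value of 2.52 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, a call lost when any of 6 of the 8 libraries was left out (all but prion preSPO replicate 1 and cured SPO replicate 1) and with the culture as a block.

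By limma camera with a preset correlation, 13 lists differed in the interaction, with 0 called with an estimated correlation and 0 by fry. Their medians, as the log2 response in cured minus that in prion libraries, were -0.23 for mitochondrial ribosomal proteins, 0.44 for glycolysis and fermentation, 0.51 for oxidative phosphorylation, 0.55 for chaperones and 0.40 for G2/M genes. The median was -0.49 for sulfur assimilation, 1.03 for histones, 0.96 for cell wall genes and 0.62 for haploid-specific genes. On log2 TPM these medians were, in this order, -0.56, 0.03, 0.14, 0.18, 0.01, -0.87, 0.61, 0.50 and 0.18. Another 4 lists changed sign on log2 TPM: cytosolic ribosomal proteins from 0.23 to -0.17, the tricarboxylic acid cycle from 0.37 to -0.01, amino acid biosynthesis from 0.34 to -0.02 and G1/S genes from 0.31 to -0.05. The median over all genes moved to -0.33 on log2 TPM and -0.19 with library size. Histones had a cured minus prion median of -1.01 in preSPO and 0.05 in SPO medium, and sulfur genes 0.60 and 0.19. Among the 13 lists the preSPO median was the larger in size except for glycolysis (-0.16 and 0.30) and cytosolic ribosomal proteins (-0.10 and 0.16). Most of these interactions thus largely repeat the preSPO difference.

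Of the 13 list calls, 4 were lost without prion preSPO replicate 2, 3 without prion preSPO replicate 1 and 3 without prion SPO replicate 2. Leaving out cured preSPO replicate 1, cured preSPO replicate 2, cured SPO replicate 1 or cured SPO replicate 2 ended 2 each, and prion SPO replicate 1 ended 1. The lists of chaperones, sulfur assimilation, histones, G1/S genes, cell wall and haploid-specific genes kept their call without any single library.

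Some medians moved by over 1.5 times without 1 library. Without prion preSPO replicate 2 they were 0.24 for glycolysis, 0.28 for oxidative phosphorylation, 0.15 for the tricarboxylic acid cycle, 0.15 for amino acid biosynthesis, 0.12 for G1/S genes, 0.63 for cell wall genes and 0.40 for cytosolic ribosomal proteins. Without cured SPO replicate 1 they were 0.15 for glycolysis, 0.20 for amino acid biosynthesis, 0.18 for G1/S genes and 0.36 for cytosolic ribosomal proteins, and without cured SPO replicate 2 they were 0.23 for G2/M genes, 0.52 for amino acid biosynthesis and 0.02 for cytosolic ribosomal proteins. Mitochondrial ribosomal proteins lay at -0.14 without prion preSPO replicate 1 and -0.11 without cured preSPO replicate 2, and cytosolic ones at 0.00 without prion preSPO replicate 1, 0.15 without cured preSPO replicate 1 and 0.14 without prion SPO replicate 1.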

How the results depend on the processing

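Leaving out pairs of libraries, leaving out TAR1 and YNL143C, and the additive model were chosen only after the results were seen. Counts of calls between states moved with many choices and those between media with few; the cause was not tested, except that leaving out libraries leaves fewer samples, and a lone library is then assumed to vary like the other groups.

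Cured against prion in preSPO medium gave 59 calls, but 432 with DESeq2, 94 on log2 TPM, 16 with only the groups compared, 142 with the replicate block, 0 at an adjusted p under 0.01, 0 to 468 without single libraries, 10 without the libraries labelled prion SPO replicate 2 and cured SPO replicate 1, and 2 without those labelled prion preSPO replicate 2 and cured preSPO replicate 1. In SPO medium the 2 calls became 4 with library size, 15 with DESeq2, 10 on log2 TPM, 5 with the stricter filter, 10 without the SPO pair and 2 to 11 without single libraries; both first calls were among the calls of each of these. The interaction had 1 call, against 2 with DESeq2-style factors, 4 with library size, 131 with DESeq2, 41 on log2 TPM, 2 with the stricter filter, 2 with the robust fit, 0 with the culture block, 2 without the SPO pair, 0 at 0.01 and 0 to 44 without single libraries. The mean over both media had 0 calls, against 1 with library size, 68 with DESeq2, 18 on log2 TPM, 3 without the SPO pair, 1 without the preSPO pair and 0 to 7 without single libraries. Between media, a 2-fold minimum left 2082 of 3380 prion calls and 2264 of 3633 cured calls; prion calls were 2171 without the SPO pair and 2192 to 3434 without single libraries, and cured calls 2764 to 3853. With Watson-Crick pairs only, the hairpin genes in preSPO medium lay at percentile 5.7, against below all random lists.

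Some list medians between states changed sign. In SPO medium, library size turned those of cytosolic ribosomal proteins to -0.038, ribosome biogenesis to -0.079, chaperones to -0.051 and sulfur genes to -0.018. The median over all genes also turned negative there, so these changes of sign are not particular to the lists. Without the SPO pair glycolysis turned to -0.124, chaperones to -0.019 and beta-oxidation to 0.023. Without single libraries ribosomal proteins ranged from -0.044 to 0.299 and beta-oxidation from -0.178 to 0.010. In the interaction ribosomal proteins ranged from 0.000 to 0.401. Over both media, ribosome biogenesis ranged from -0.016 to 0.273, iron genes from -0.002 to 0.315 and cell wall genes from -0.244 to 0.008; without the preSPO pair ribosome biogenesis lay at -0.008, without the SPO pair iron genes at -0.024, and with library size mitochondrial ribosomal proteins at -0.010.

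Named genes called in the main comparisons kept their direction and call in 1311 of 1491 checks, with 0 reversed. The lost checks all fell on the genes named between states in preSPO medium, from 7 for SUL2 to 11 for ECM33, and on AI2, with 10. Genes named between media, VTS1 among them, lost 0, so the pooled share does not describe the genes named between states. Called lists kept theirs in 1064 of 1295 checks, with 16 reversed. Of the reversed list checks 5 came from library size scaling, which also moved the median over all genes. The lowest sum of counts, in cured SPO replicate 1, limits detection to 0.680 CPM there.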

Other observations

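The tests of exchange, repression and preSPO RNA for MET17, of the A run, of the position along the first component, of MET17 absence, and the splits were chosen only after the results were seen; the correction for coding length and GC was not. For the exchange and for MET17 absence a second condition was added after the values were seen, and without it both tests would have gone with those explanations.

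In SPO medium SIT1, a siderophore transporter, rose by 3.88 in prion libraries and 3.83 in cured ones. Of 27 iron genes 13 rose and 5 fell in prion libraries and 10 rose and 4 fell in cured ones, with medians that turned from 0.49 and 0.31 to -0.12 and -0.63 on log2 TPM. Of 28 autophagy genes 14 rose and 4 fell in prion libraries and 10 rose and 1 fell in cured ones, with ATG34 at 3.45 and 3.34 and medians that turned from 0.59 and 0.36 to -0.03 and -0.57 on log2 TPM. Of 20 glycolysis and fermentation genes 3 rose and 3 fell in prion libraries and 4 rose and 2 fell in cured ones, with HXK2, a hexokinase, at -2.10 and -1.44. These calls are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. On log2 TPM the median over all genes turned negative as well in both states.

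In SPO medium MET17 was nearly absent from the library labelled prion replicate 2 and present in the one labelled cured replicate 1 (1 and 447 counts), although their same-numbered preSPO libraries had 3867 and 0, which cultures of one state that differ at MET17 would not give if libraries of one state and number share a culture. The tables argue against repression along with other sulfur genes, since the median log2 ratio of the sulfur list of prion SPO replicate 2 over replicate 1 was 0.09 (SE 0.0427) where repression would need a value under -1, and against prion preSPO RNA as the source in cured SPO replicate 1, where 25.9% would be needed and 43 genes that fell over 8-fold in prion libraries, from at least 10 CPM, had a median log2 ratio to the level this share brings of -1.44 (SE 0.248) in place of at least 0. An exchange of the libraries labelled prion SPO replicate 2 and cured SPO replicate 1 stays open: over 59 genes called in preSPO medium the score for the cured state was 0.152 higher in the first (95% bootstrap interval 0.0699 to 0.236 over genes of 2 single libraries), but the scores of 0.002 and 0.055 in prion and -0.097 and 0.041 in cured SPO replicates 1 and 2 also go with the replicate number. With an exchange go the Spearman correlations of cured SPO replicate 1, highest with prion SPO replicate 1 (0.980, against 0.958 with cured SPO replicate 2). So do those of cured SPO replicate 2, highest with prion SPO replicate 2 (0.979). Both pairs also share their replicate number, which went with values across states in SPO medium (correlation of deviations 0.395). These correlations therefore do not tell an exchange from an effect of the replicate number. Against an exchange, the libraries labelled prion SPO correlated best with each other (0.987). An exchange among preSPO libraries had no test of its own and may also explain the pattern. RNA of prion SPO cells in cured SPO replicate 1, also without a test, would leave prion SPO replicate 2 unexplained. Such RNA would have to be most of a library, at 101 CPM of MET17 against 141 CPM in prion SPO replicate 1. The Ty frames had 0 counts in cured SPO replicate 1, but they were called for their absence from the cured SPO libraries. Their copies are not resolved either, so they do not bear on this source.

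YNL143C held 8.94% of the counts of cured SPO replicate 2 (95% Wilson interval 8.93 to 8.94) and at most 0.192% (0.189 to 0.194) of any other library. Reads of poly(A) tails may have been assigned to it, since it has a run of 32 A bases in its coding sequence, with 0 runs as long among the other targets searched. The target with the next longest run, MTC7 with 25, was also highest in that library, at 288 CPM against at most 180 CPM elsewhere. Targets with runs of 14 to 19 were not higher there, at 0.83 to 0.975 times the mean of the other SPO libraries. No biological explanation was tested.

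The higher sulfur genes in the libraries labelled cured preSPO were also weighed. Coding length and GC as the cause are argued against, since 116% of the list median remained (0.60 before, 0.69 after) once their trend was removed. The position of the cultures along the first component, that of the medium, predicted 7.62% (SE 21.8) of the observed mean, an error too wide to decide. In SPO medium the sulfur median of replicate 2 over replicate 1 was 0.211 (SE 0.0811) in the libraries labelled cured and 0.09 in those labelled prion, against up to 0.182 between preSPO replicates, which share their MET17 status. In preSPO medium the absence of MET17 and the cured state coincide in all 4 libraries, so these explanations cannot be told apart and either may hold.

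For the mean over both media, the 18 splits within medium are too few for a share under 0.05; the real split gave 0 calls and the highest other 40. That split kept the labelled preSPO groups and divided the SPO libraries by replicate number, which is also the division by MET17 reads and the one an exchange of prion SPO replicate 2 and cured SPO replicate 1 would give. Its count includes the preSPO difference and does not show a structure of the samples in SPO medium. The division itself gave 2 calls in SPO medium, as did the labels, and its other orientation gave 0 calls over both media. With that division of the SPO libraries the labelled preSPO comparison gave 143 calls, against 59 with the labelled SPO groups and 142 with the replicate number as a block. With this block the real contrast over both media gave 0 calls (839 genes at an unadjusted p under 0.05 by edgeR). In preSPO medium the labelled split gave 59 calls and the highest of the other splits 0, and in SPO medium these were 2 and 2.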
